A study of Homo sapiens with 18 samples.

How the data were processed

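RNA sequencing libraries of the human breast cancer cell line Cal51 were grouped by the labels, 3 libraries per group. The comparisons used 12 libraries from cells treated for 8 h with DMSO, fenofibrate, ezetimibe or both drugs. The 6 libraries of PKM2 knockout cells and their control have no values in the deposited tables used here and are not analysed here. The labels number the replicates from 1 to 3 in each group, and nothing in them says that the replicates were separate cultures, so the p-values can measure technical spread alone.

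The submitters' processing notes name fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the genome build hg38. The tool of the authors' comparison is not given in the sources used here. Each deposited table holds, per the file headers, the signal of 6 libraries, the log2 fold change and the p-value of each gene, with its position, biotype and length. The signal was found from the values to be read counts divided by one factor per library, which the authors set separately in each table. The factors ran from 0.896 to 1.12, and 100% of the values divided to whole reads within 0.001. The log2 fold changes and p-values are the authors' own, as deposited, and the adjusted p-values follow the Benjamini-Hochberg method over 12215, 13596 and 19944 genes in the fenofibrate, ezetimibe and combination tables, numbers inferred from the ranks of the p-values. Of these genes 854, 4559 and 7923 had a p-value at or under the largest one listed, whatever their fold change. The inferred numbers gave a whole rank (within 0.02) for 58.8%, 89.1% and 89.7% of the listed p-values used. The number for fenofibrate, and what rests on it, is therefore the least certain. The tables keep only genes with an absolute log2 fold change above 1 and an adjusted p under 0.05, so no gene outside them could be tested. The DMSO libraries held equal reads in every table (1452 of 1452 pairs of gene and library). Positions were compared with GENCODE release 29, and 3642 of 3647 genes had equal coordinates.

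The choices in this paragraph were made before the data were examined, except where stated. Each comparison was fitted with limma 3.58.1 (with trend, in R 4.3.3) on log2 of the value plus 1, with Benjamini-Hochberg adjustment over the genes of the table and a threshold of 0.05. The added 1 draws log2 fold changes of genes with few reads towards 0. Limma also compares means of log2 values, so some of its changes are larger than the authors'. PLA2G3 with fenofibrate, for example, had 3.81 by limma and 3.72 by the authors. All tests of single genes are 2-sided. For genes in more than 1 table the tables were put on one scale through their shared DMSO libraries (the mean ratio was 0.975 between the fenofibrate and combination tables and 1.00 between the ezetimibe and combination tables), and limma tested each treatment against the others and the combination against the sum of the single-drug changes. With 3 libraries against 3 an exact permutation test cannot give a 2-sided p under 0.1, so none is used for single genes.

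For 33 gene lists with 902 memberships, all matched to a gene identifier, members in each table were counted by direction. A Fisher's exact test (2-sided) compared the split of higher and lower members with the rest of the same table in the 48 cases with at least 2 listed members. The number of members listed was tested with an exact hypergeometric test (1-sided, 198 tests, adjusted together), which was chosen after the tables were seen, with all members counted as tested. That counting alone makes the test conservative. The hypergeometric and Fisher's tests take genes as independent, however, and members of a list that change together can make their p-values too small. The adjusted p given for a list is that of the hypergeometric test unless a split or Fisher's test is named. Whether members listed with a single drug were also in the combination table was tested against its other genes with Fisher's exact test (15 tests), also chosen after the tables were seen. The lists were fixed before the tables were seen and cover lipid metabolism, glycolysis and hypoxia, stress responses, growth arrest and cell death, the cell cycle, ribosomes, mitochondria, inflammation, matrix, cell type markers, lysosomes, drug metabolism, splicing, ferroptosis, clock genes and Hippo signalling.

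Genes named with values were the 10 largest rises and 10 largest falls of each table among protein-coding genes with a symbol, a mean of at least 50 and no overlap between treated and DMSO libraries (8 falls qualified for fenofibrate), up to 4 members of each list with the largest change, and PPARA, NPC1L1 and PKM where listed. Other genes, such as those singled out in comparisons between tables or named as list members, were chosen after their values were seen. Folds are ratios of mean values. Where DMSO had 0 reads the fold is a lower bound on a floor of 3 reads over the group, and where it had 1 to 3 reads the ratio has a 95% exact interval. Intervals and floors cover counting error alone.

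Alternatives were other pseudocounts, a mean value of at least 50, limma without trend, adjusted p 0.01 (limma's for totals, the authors' for lists and overlaps), protein-coding genes alone, the replicate number as a block, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. The limma step was tested on simulated data of the same size and depth. In 102, 472 and 3508 simulated genes it recovered 80%, 72% and 68% of changes of 1 on the log2 scale and 100%, 96% and 87% of changes of 2, and it called 0 of 82, 2 of 372 and 5 of 3308 unchanged genes. Most simulated genes were unchanged, whereas every gene in the deposited tables had been listed as changed, so these rates need not hold for those tables. Tables were handled in Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1.

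Results for some list genes are not reported here.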

Results

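RNA was sequenced from Cal51, a human breast cancer cell line. The series holds 18 libraries in 6 groups of 3. The comparisons use the 12 libraries of 4 groups treated for 8 h: DMSO (the solvent control), fenofibrate (a lipid-lowering fibrate that activates the nuclear receptor PPARα), ezetimibe (an inhibitor of the sterol transporter NPC1L1) and both drugs together, here called the combination. The labels give no dose. The 6 libraries of the PKM2 knockout and its control are not analysed here. Each of 3 tables sets one treated group against the same 3 DMSO libraries and lists only genes called by the authors, with an absolute log2 fold change above 1 and an adjusted p under 0.05. Each library held 40113 to 108822 reads in the genes of the fenofibrate table, 185127 to 339263 in those of the ezetimibe table and 2550718 to 3265200 in those of the combination table. The total depth of each library is unknown. Values are normalised read counts, given as mean ± SD over 3 libraries, treated before DMSO. Log2 fold changes are given ± SE from limma, and positions are on hg38. A gene absent from a table can have been unchanged, changed by less than the listing threshold or too low to test, so absence is written as "not listed".

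The first comparison asked what fenofibrate alone did to gene expression after 8 h. The genes past the listing threshold with fenofibrate were few and mostly higher, and the cholesterol list had the most members among them. The direction of smaller changes is unknown. The authors' deposited table listed 102 genes, 93 higher and 9 lower, and 18 of the 30 genes on the list of cholesterol synthesis and SREBP2 targets were among those higher. INSIG1, which holds the SREBP complex in the endoplasmic reticulum (ENSG00000186480, chromosome 7, 155297776 to 155310235), rose 4.39-fold, to 1560.2 ± 84.4 against 355 ± 36.9 (log2 2.13 ± 0.10, adjusted p = 3.25e-07). Among protein-coding genes with a mean of at least 50 and no overlap between treated and DMSO libraries the largest rise by the authors' fold change was that of PLA2G3, a secreted phospholipase (chromosome 22, 31134809 to 31140607), at 13.4-fold, from a low level (138 ± 17.9 against 10.3 ± 7.44). The largest fall among them was that of TXNIP, an inhibitor of thioredoxin and of glucose uptake (chromosome 1, 145992435 to 145996600), whose log2 fold change was -2.39 ± 0.15 (80.9 ± 13.1 against 425 ± 10.3, adjusted p = 8.84e-07).

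The cholesterol genes that rose with fenofibrate spanned the pathway from its early to its last steps. Among them were MSMO1, a sterol methyl oxidase (1844 ± 204 against 427 ± 64.7, 4.32-fold), FDFT1, which makes squalene (3197 ± 317 against 782 ± 37.5, 4.09-fold), and DHCR7, which makes cholesterol in the last step (3785 ± 403 against 934 ± 47.5, 4.05-fold). HMGCS1, MVK, MVD, IDI1, SQLE, LSS, NSDHL, HSD17B7, STARD4 and SREBF2 were also among the 18. The 18 genes had a median log2 fold change of 1.57 and a range from 1.00 to 2.13, and 0.228 of the 30 members would be listed as higher by chance (hypergeometric adjusted p = 2.06e-29). The fatty acid synthesis list followed with 4 of 22 members higher (adjusted p = 0.000242). These were FADS2 and FADS1, desaturases of polyunsaturated fatty acids, SCD, which makes monounsaturated fatty acids (21496 ± 925 against 8398 ± 567, 2.56-fold), and PNPLA3, a lipid droplet protein. The list of PPARα targets and fatty acid oxidation had 0 of 44 members higher and 1 lower, TXNIP. NPC1L1, the target of ezetimibe named in the study's title (chromosome 7, 44512535 to 44541315), was listed as higher at a low level (45.2 ± 2.36 against 12.2 ± 6.94), and PPARA and PKM were not listed in any of the 3 tables.

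A set of stress genes also rose with fenofibrate. The list of ATF4 and amino acid response genes had 9 of 36 members higher and 0 lower (adjusted p = 1.30e-10), including NUPR1, a stress-induced chromatin protein (422 ± 25.8 against 65 ± 28.9, 6.49-fold), TRIB3, a pseudokinase (2904 ± 415 against 836 ± 23.8, 3.47-fold), and the asparagine synthetase ASNS (78.6 ± 11 against 29 ± 5.17, 2.71-fold). The NF-κB list had 3 of 26 higher, the chemokines CCL20, CXCL8 and CXCL2 (adjusted p = 0.00881). The hypoxia list had 3 of 21 higher, EPAS1 and PFKFB4 among them (adjusted p = 0.00485). Of the NRF2 list 2 of 24 members rose, HMOX1 and ABCC3, which did not pass for the list (adjusted p = 0.108). CYP1A1, a cytochrome induced through the aryl hydrocarbon receptor, rose 3.95-fold (567 ± 13 against 144 ± 2.49). ARRDC4, an arrestin-domain relative of TXNIP, fell (log2 -1.73 ± 0.15, 85.4 ± 3.41 against 288 ± 46.5), as did the kinetochore motor CENPE (606 ± 157 against 1337 ± 207), the only one of 39 genes of the G2/M list in this table. Limma called all 102 listed genes (93 higher and 9 lower), and in 100 of them no treated library overlapped a DMSO library. By chance 10% of unselected genes would show this. The authors had picked these genes on the same libraries, so that share is no measure for them. For the same reason the limma p-values describe how firmly listed genes differ and are not independent evidence.

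The second comparison asked what ezetimibe alone did. Its table was longer than that of fenofibrate, with a stress response of the endoplasmic reticulum on one side and fewer mitotic transcripts on the other. The authors' deposited table listed 472 genes, 367 higher and 105 lower. Of the 36 ATF4 genes 18 were higher and 0 lower (adjusted p = 8.84e-18), and of the 23 genes of the unfolded protein response 9 were higher and 0 lower (adjusted p = 7.99e-08). Of the 39 genes of the G2/M list 15 were lower and 0 higher (adjusted p = 1.57e-20). HSPA5, the main chaperone of the endoplasmic reticulum (ENSG00000044574, chromosome 9, 125234853 to 125241330), rose 2.76-fold, to 50818 ± 279 against 18416 ± 420.2 (log2 1.46 ± 0.04, adjusted p = 1.09e-11).

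The 10 largest rises with ezetimibe by the authors' fold change, in protein-coding genes with a mean of at least 50 and no overlap between treated and DMSO libraries, included those of KLHDC7B, LAMP3, BHLHA15, FAM129A and ALDH1L2. KLHDC7B (chromosome 22, 50545891 to 50551023) rose 57.7-fold (606 ± 43.6 against 10.5 ± 7.22), LAMP3, a lysosomal membrane protein, 46.3-fold (155 ± 30.3 against 3.35 ± 1.31), and BHLHA15, a transcription factor of secretory cells, 25.6-fold (139 ± 17.1 against 5.44 ± 3.10), all from DMSO levels of few reads. FAM129A, a stress-induced protein, rose 16.6-fold from a higher level (1997 ± 18.7 against 120.3 ± 13.6), and ALDH1L2, a mitochondrial folate enzyme, 6.55-fold (1638 ± 85.5 against 250.0 ± 31.9). The ATF4 members TRIB3 (5089.5 ± 131 against 859.7 ± 27.6) and STC2, a secreted glycoprotein (2649 ± 169 against 560.4 ± 34.3), rose 5.92-fold and 4.73-fold. In the unfolded protein response list the co-chaperone DNAJB9 rose 4.27-fold (1056 ± 13.3 against 247 ± 17.6) and the ubiquitin ligase SYVN1 2.36-fold (1819.5 ± 37 against 769.7 ± 21.3). The NF-κB list had 8 of 26 members higher (adjusted p = 4.40e-06), among them the chemokine CXCL8 (1223 ± 39.1 against 333 ± 39.4), and 4 of the 8 had a mean value of at least 50. The NRF2 list had 7 of 24 higher (adjusted p = 2.84e-05), among them HMOX1, which breaks down haem (140.2 ± 9.02 against 28.4 ± 2.29), and the cystine transporter SLC7A11 (5453 ± 173 against 1799 ± 139), while AKR1C3 was lower at a low level.

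The largest falls with ezetimibe by the same rule included ID3 (chromosome 1, 23557918 to 23559794) and ID1, inhibitors of basic helix-loop-helix transcription factors. ID3 had a log2 fold change of -2.35 ± 0.09 (623 ± 28 against 3182 ± 377, adjusted p = 5.54e-10), and ID1 of -1.60 ± 0.07 (1138 ± 32.8 against 3444 ± 206). FOXJ1, a regulator of ciliated cells, and AQP1, a water channel, fell at lower levels (log2 -2.26 ± 0.38 and -2.01 ± 0.20). Mitotic genes fell as well. DLGAP5, a spindle protein, fell by 1.37 on the log2 scale (824 ± 44.3 against 2139.6 ± 165) and TOP2A, the topoisomerase of mitotic chromosomes, by 1.24 (4104 ± 175 against 9728 ± 819). The mitotic kinase AURKA went to 1069 ± 8.10 against 2551 ± 76.6. Their list held all its 15 changed members on the lower side, unlike the rest of the table (Fisher's exact test, 2-sided, adjusted p = 1.70e-09). None of the 41 genes of the S phase list was listed here.

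Sterol genes rose with ezetimibe as well. The cholesterol list had 8 of 30 members higher and 0 lower (adjusted p = 1.29e-05), among them the sterol carrier STARD4 (chromosome 5, 111496033 to 111512590, 355 ± 33.2 against 139.9 ± 13.5) and INSIG1 (906 ± 35.1 against 365 ± 36.6, 2.48-fold). Of the fatty acid synthesis list only PNPLA3 was listed, and of the PPARα list only PLIN5, a lipid droplet protein at a low level (37.4 ± 13 against 13.2 ± 3.85). The hypoxia list had 5 of 21 higher, among them EPAS1 and the collagen cross-linking enzyme LOX (adjusted p = 0.00218). The drug metabolism list had 4 of 18 higher (adjusted p = 0.00977), all known to respond to the aryl hydrocarbon receptor: CYP1A1 (1412 ± 44.2 against 148 ± 2.19, 9.56-fold), AHRR, TIPARP and CYP1A2. The ferroptosis list had 4 of 18 higher (adjusted p = 0.00977), AIFM2 with HMOX1 and SLC7A11, which are also on the NRF2 list, and CHAC1, which is also on the ATF4 list. NPC1L1 was again listed as higher at a low level (37.6 ± 4.55 against 12.5 ± 7.09). CDH5, an endothelial marker, was listed as lower at very low values (10.1 ± 3.38 against 26.9 ± 10.3, log2 -1.31 ± 0.39, adjusted p = 0.00606), and without DMSO replicate 2 it was no longer called (log2 -1.03, adjusted p = 0.0559). Limma called 471 of the 472 listed genes, and 464 had no overlap between treated and DMSO libraries. The 10% by chance holds for unselected genes and is no measure here, as these were listed on the same libraries. Of the 295 called genes with a mean value of at least 50, 216 were higher (73.2%).

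**Figure D1:**
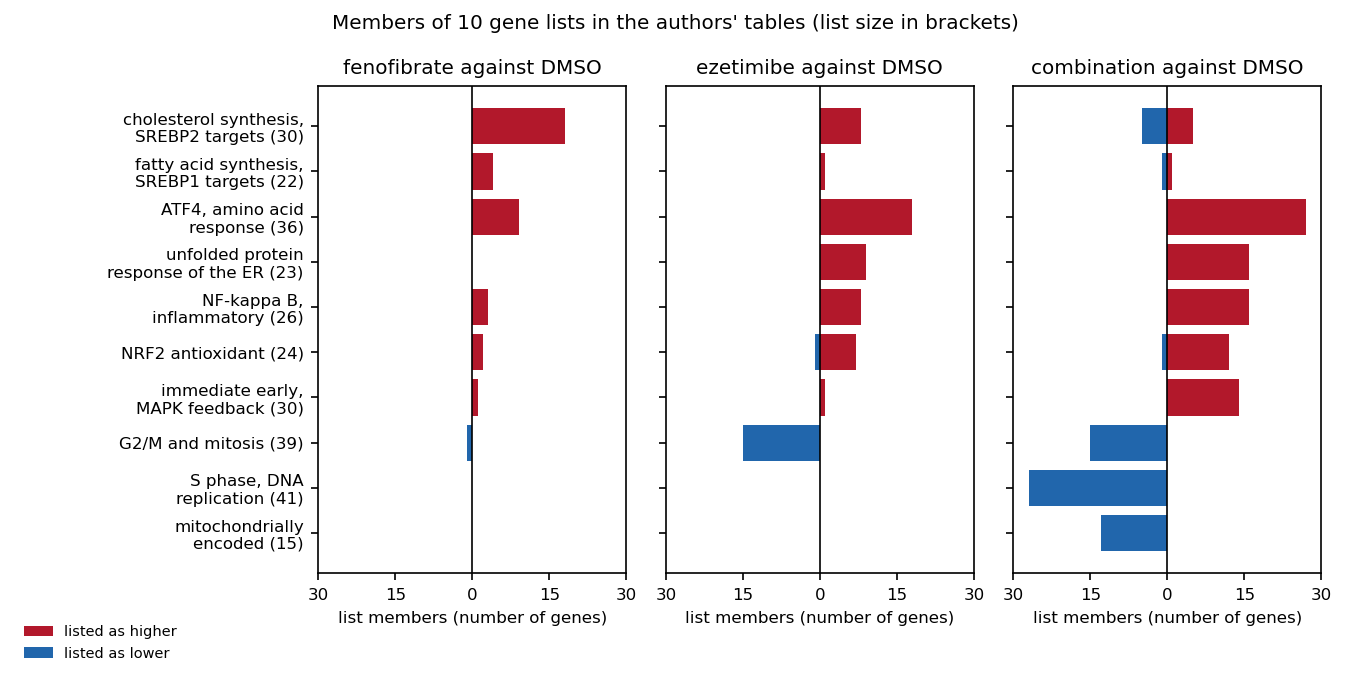
Number of members of 10 gene lists that the authors' deposited tables hold as higher (bars to the right) or lower (bars to the left) than DMSO, for fenofibrate, ezetimibe and the combination, with each list's size in brackets. The cholesterol list has 18 higher members with fenofibrate and 5 higher and 5 lower with the combination, while the S phase list has 27 lower members with the combination and none with either single drug.

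The third comparison asked what both drugs did together, the treatment that the study's title is about. Its table was the longest of the 3, with stress and inflammatory responses and lower levels of DNA replication and mitochondrially encoded transcripts. The authors' deposited table listed 3508 genes, 2058 higher and 1450 lower. ATF3, a stress-induced transcription factor (ENSG00000162772, chromosome 1, 212565334 to 212620777), rose 48.8-fold, to 2827 ± 278 against 57.9 ± 5.66 (log2 5.58 ± 0.13, adjusted p = 1.70e-09). UHRF1, which maintains DNA methylation during replication (chromosome 19, 4903080 to 4962154), had a log2 fold change of -2.74 ± 0.12 (617 ± 60.2 against 4128 ± 409, adjusted p = 2.92e-08), and MT-CO1, a subunit of cytochrome oxidase (chromosome MT, 5904 to 7445), one of -2.16 ± 0.15 (39079 ± 5229 against 174126 ± 21607).

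The ATF4 list had 27 of 36 members higher with the combination and 0 lower (adjusted p = 3.68e-18), a split that differed from the rest of the table (Fisher's exact test, 2-sided, adjusted p = 1.41e-05). After ATF3, the largest rises among them were those of GDF15, a stress cytokine (chromosome 19, 18374731 to 18389176, 15238 ± 2109.7 against 667 ± 61, 22.8-fold), NUPR1 (1133 ± 214 against 66.7 ± 29.8, 17-fold) and TRIB3 (12801 ± 1908 against 857 ± 26.8, 14.9-fold). The unfolded protein response list had 16 of 23 members higher and 0 lower (adjusted p = 4.68e-10), with a split that differed from the rest of the table (Fisher's exact test, adjusted p = 0.00260). HSPA5 reached 143891 ± 5378 against 18369.9 ± 437 (7.83-fold), DNAJB9 3369 ± 44 against 246 ± 17.5 (13.7-fold) and ERN1, the stress sensor IRE1, 2226 ± 405 against 209.5 ± 12 (10.6-fold). The NRF2 list had 12 of 24 higher (adjusted p = 1.54e-05), including HMOX1 (472 ± 76.7 against 28.3 ± 2.32, 16.7-fold) and OSGIN1 (4505 ± 629 against 729 ± 148), and AKR1C3 lower at a mean under 50. AKR1B10 had 0 reads in DMSO and was at least 5.36-fold higher, on a floor of 3 reads over the group, and its limma log2 fold change of 2.39 became 3.10 without combination replicate 3. Heat shock genes of the cytosol and mitochondria went both ways. Of the 15 heat shock genes HSPA6 was higher (119 ± 15.7 against 1.70 ± 1.30), while HSP90AA1 (14289.5 ± 451 against 46981 ± 3063), HSPE1 and DNAJA1 were lower, and the list passed in neither direction (adjusted p = 1 for higher and 0.512 for lower).

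Inflammatory and early response genes rose with the combination. The NF-κB list had 16 of 26 members higher and 0 lower (adjusted p = 6.66e-09), with a split unlike the rest of the table (Fisher's exact test, adjusted p = 0.00260). IL1A, an inflammatory cytokine (chromosome 2, 112773915 to 112784590), rose 34.8-fold (578 ± 36.3 against 16.6 ± 7.70), CXCL3 25-fold (223 ± 15 against 8.94 ± 8.36) and CXCL8 12.2-fold (4049.9 ± 98.2 against 332 ± 39.6). The log2 fold change of CXCL3, 4.90, became 4.19 without DMSO replicate 2 and 5.57 without DMSO replicate 3. The list of immediate early genes had 14 of 30 higher and 0 lower (adjusted p = 6.64e-06, split adjusted p = 0.00389), among them FOSL1 and FOSB of the AP-1 family (1625 ± 248 against 192 ± 19.3 and 72.9 ± 5.89 against 8.76 ± 2.04) and MYC (7419 ± 85.9 against 1202 ± 62.4, 6.17-fold). Of the other 36 genes on the MYC target and ribosome biogenesis list 2 were listed, RRP12 and RRP9, and the list did not pass (adjusted p = 1). The p53 list had 9 of 24 higher and 1 lower (adjusted p = 0.00399), led by the growth arrest gene GADD45A (chromosome 1, 67685061 to 67688338, 10433 ± 211 against 538 ± 32.6, 19.4-fold), with the death receptor TNFRSF10B also higher (8946 ± 63.7 against 1730.5 ± 24). It shares higher members with the ATF4 and BCL2 family lists. Of 15 genes of the BCL2 family the death-promoting HRK (121 ± 28.6 against 12.6 ± 9.47), BBC3 (701 ± 36.2 against 215 ± 67.6), BIK and PMAIP1 were higher and the survival gene BCL2 was lower, without passing as a list (adjusted p = 0.378). The glucocorticoid and clock list had 6 of 11 higher (adjusted p = 0.00365), led by TSC22D3, a glucocorticoid-induced repressor (1004 ± 178 against 153 ± 23.9), and the phosphatase DUSP1 (1728 ± 82.7 against 289 ± 27.7), which is also on the immediate early list.

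Genes of DNA replication fell with the combination. The S phase list had 27 of 41 members lower and 0 higher (adjusted p = 1.25e-19), with a median log2 fold change of -1.48 and a split unlike the rest of the table (Fisher's exact test, adjusted p = 1.70e-09). E2F2, an activator of S phase genes, fell by 2.51 on the log2 scale (183 ± 31.6 against 1041 ± 25.2), and the G1/S cyclins CCNE2 and CCNE1 fell by 2.31 (66.1 ± 8.86 against 334 ± 62.2) and 2.24 (107 ± 14 against 506 ± 21.4). The G2/M list had 15 of 39 members lower and 0 higher (adjusted p = 6.66e-07, split adjusted p = 2.02e-05), among them ANLN, which acts in cytokinesis (1867 ± 491 against 6609 ± 962), and TOP2A (2873 ± 709 against 9703 ± 826). No histone gene was listed as lower. Of 39, 4 were higher, of which HIST1H2AC (123 ± 22.6 against 50.7 ± 13.5) and H1F0, a histone of cells that do not divide (3629.7 ± 274 against 1574 ± 182), had means of at least 50, and the list did not pass (adjusted p = 1). HIST1H2BG had 0 reads in DMSO and was at least 7.37-fold higher.

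All 13 mitochondrially encoded protein-coding genes were lower with the combination. Of the list of 15, which also holds the ribosomal RNA genes MT-RNR1 and MT-RNR2, these 13 were the listed members (adjusted p = 4.55e-12, split adjusted p = 9.56e-05). Both tests count the genes as independent, though they belong to the same genome and fell together, so these p-values can be far too small. The log2 fold changes of the 13 genes ran from -2.58 to -1.67 with a median of -2.01. MT-ATP8 (92.4 ± 16.9 against 556 ± 96.3) fell the most, and MT-CO2, another subunit of cytochrome oxidase, went to 11869 ± 2311 against 60757 ± 8311 and MT-ND5, a subunit of complex I, to 9538 ± 921 against 40808 ± 4583. Summed over the 13 genes the normalised read count was 179040 ± 19284.9 against 687305 ± 90233.5. Neither single-drug table held a gene of the mitochondrial genome. Of the 56 nuclear genes of oxidative phosphorylation 5 were lower and 0 higher (adjusted p = 1, split adjusted p = 0.0641), NDUFB3, ATP5MC3, COX7B, UQCRH and UQCRB. None of the 58 ribosomal protein genes was listed in any of the 3 tables.

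**Figure D2:**
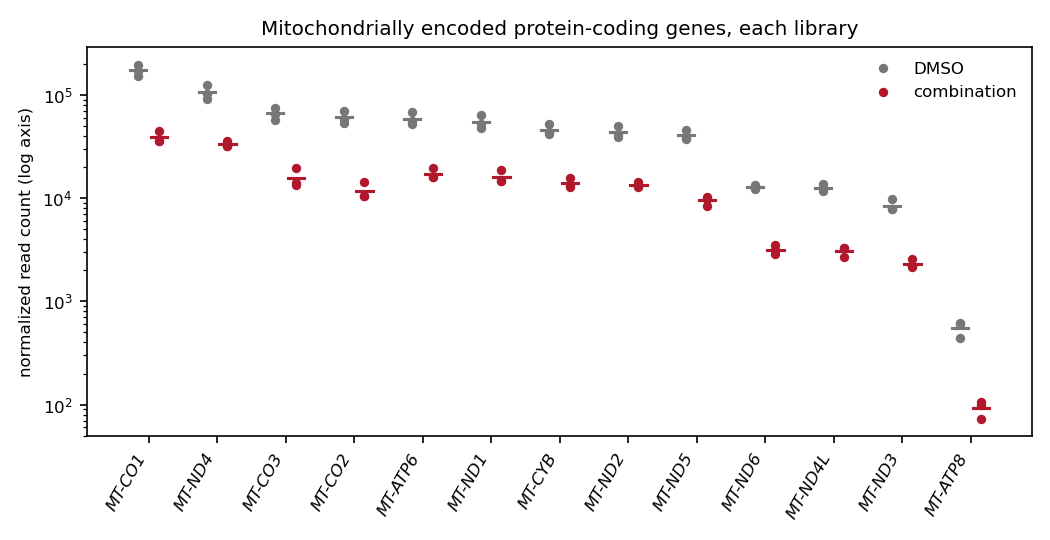
Normalised read count (log axis) of the 13 mitochondrially encoded protein-coding genes in each of the 3 DMSO and 3 combination libraries, with points for libraries and lines for group means. For every gene the combination libraries lie under the DMSO libraries, with log2 fold changes from -2.58 to -1.67.

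The rise of sterol synthesis genes seen with each single drug was not found for the list with the combination. It had 5 of 30 members higher and 5 lower (adjusted p = 0.845 for higher and 0.378 for lower). Among those higher were STARD4 (603 ± 126 against 139.5 ± 13.6), HSD17B7, CYP51A1 and NPC1, which carries cholesterol out of lysosomes (chromosome 18, 23506184 to 23586898, 1871 ± 68.5 against 567 ± 34.9, 3.30-fold), and among those lower MYLIP (52.9 ± 2.60 against 164 ± 14.8, log2 -1.61 ± 0.18, adjusted p = 1.14e-05), LBR, ACAT2 and TMEM97. Of the 18 cholesterol genes that fenofibrate raised, 4 were in the combination table, 3 of them in the same direction, against 61 of the 84 other fenofibrate genes (Fisher's exact test, 2-sided, p = 0.000101, adjusted over 15 such tests p = 0.00151). The 14 not listed, INSIG1, MSMO1, FDFT1 and DHCR7 among them, therefore had a log2 fold change under 1 in size or did not pass the authors' test. Of the 8 cholesterol genes that ezetimibe raised 3 were in the combination table, against 356 of 464 others, which did not pass after adjustment (Fisher's exact test, p = 0.0217, adjusted p = 0.0734). The fatty acid synthesis list had LPIN1 higher and SCD5 lower (401 ± 28.6 against 1219.9 ± 56.2), and the LXR list PLTP higher and MYLIP and LPCAT3 lower. The PPARα list had 3 of 44 higher, FGF21 and PLIN5 among them, and it did not pass (adjusted p = 1). NPC1L1 was not listed with the combination.

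**Figure D3:**
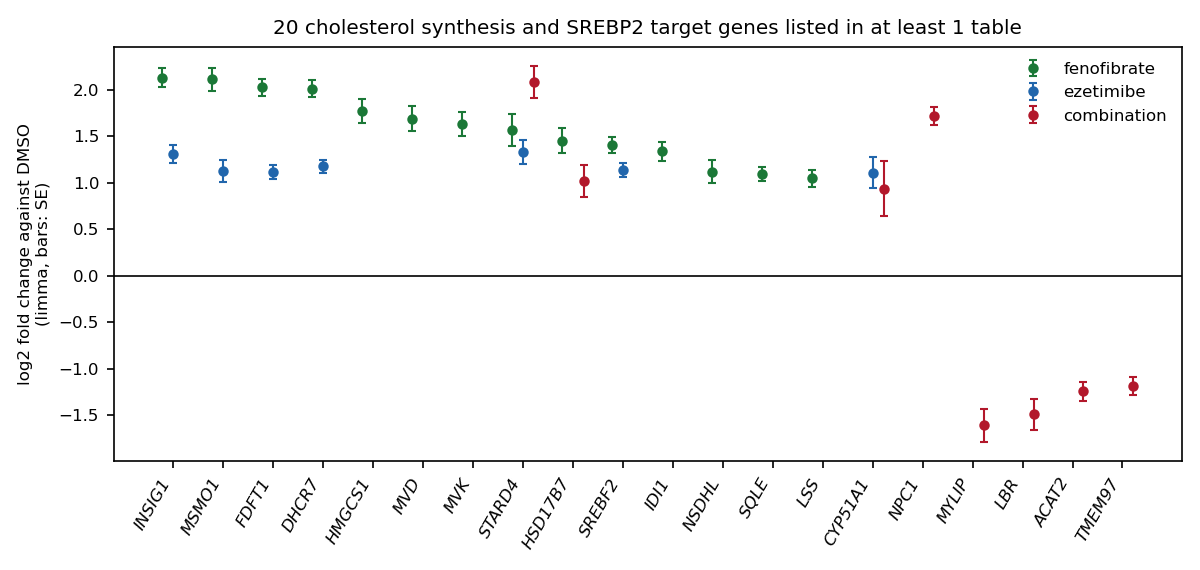
Log2 fold change against DMSO (limma, bars show SE, 3 libraries per group) of 20 cholesterol list genes found in at least 1 of the 3 tables, by treatment. A missing point means that the table does not list the gene. The 14 genes shown for fenofibrate lie between 1.05 and 2.13, and MYLIP lies at -1.61 with the combination.

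Several lists had members on both sides or did not pass with the combination. The hypoxia list had 6 of 21 higher and 2 lower (adjusted p = 0.118), with EPAS1 at 930.4 ± 128 against 35.7 ± 18.4 (26.1-fold) and VEGFA, a vascular growth factor, at 3559 ± 321 against 956 ± 112. The glycolysis list had HK2 (4304 ± 729 against 1165 ± 81.2) and SLC2A3 higher and PGAM1 (3134 ± 455 against 7553 ± 205), PDK3, LDHA and TPI1 lower (adjusted p = 1 and 0.531). SLC2A3 rested on 40 against 2 reads, a ratio of 20.1 with a 95% exact interval from 5.21 to 172 for counting error alone. The list of autophagy and lysosome genes had 6 of 32 higher and 1 lower (adjusted p = 0.531), including the autophagy receptor SQSTM1 (27790.2 ± 3031 against 5655 ± 534) and WIPI1 (758 ± 41.2 against 84.8 ± 14.5). The Hippo list had 4 of 16 higher (adjusted p = 0.437), ANKRD1 (3878 ± 91 against 524 ± 30.8), CTGF, CYR61 and AMOTL1. The drug metabolism list had CYP1A1 (2641 ± 208 against 147 ± 2.20) and TIPARP higher and CYP1B1 lower (adjusted p = 1). The ferroptosis list had 6 of 18 higher and LPCAT3 lower (adjusted p = 0.0590).

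The largest rises with the combination, by the authors' fold change among protein-coding genes with a mean of at least 50 and no overlap between treated and DMSO libraries, were in genes nearly silent in DMSO. LURAP1L went from 1 read to 341 over the group, a ratio of 343 with a 95% exact interval from 61.1 to 13570.3 for counting error alone. KLHDC7B reached 1875 ± 111 against 10.5 ± 7.20, LAMP3 507 ± 40.5 against 3.34 ± 1.31 and BHLHA15 491 ± 17.2 against 5.42 ± 3.09, and DACT1, a WNT pathway antagonist, OSCAR, NGFR, the neurotrophin receptor, TMEM125, HSPA6 and TNFRSF9 completed the 10. The largest falls by the same rule were those of METTL7A (log2 -4.08 ± 0.23, 12 ± 2.00 against 217 ± 10.9), SAMD11, WDR72, EMILIN3 and PCDH17, a protocadherin (15.7 ± 4.12 against 218 ± 11.6), followed by MEOX1, SEMA3F, CSPG5, S1PR5 and GAL3ST1. Limma called all 3508 listed genes, and 3473 had no overlap between treated and DMSO libraries. Their listing on the same libraries favours this, so the 10% by chance of unselected genes is no measure for them. The excess of higher genes, 58.7% of those listed, was carried by genes with low values: of the 2303 with a mean of at least 50, 1128 were higher and 1175 lower (49.0% higher).

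The design also allows the combination to be set against each drug on the same genes, since the 3 tables share their DMSO libraries. A gene is in both tables only if its change with the combination also exceeded 1 on the log2 scale, as for 359 of 472 ezetimibe genes and 65 of 102 fenofibrate genes, so genes whose change shrank below that are missing and the counts do not show how often the combination took a change further. Of the 359 shared with ezetimibe, 227 differed between the 2 treatments, 225 of them further from DMSO with the combination, 1 nearer (LINC02535) and 1 on the opposite side (FNDC10). Of the 65 shared with fenofibrate, 51 differed, 46 further from DMSO, 1 nearer (HSD17B7) and 4 on the opposite side. HSPA5 was higher with the combination than with ezetimibe (combination 143891 ± 5378 against 50689 ± 278 with ezetimibe on one scale, adjusted p = 7.37e-11), and TOP2A was lower (log2 difference -0.54 ± 0.15, adjusted p = 0.00593). ATF3 exceeded its ezetimibe level by 4.11 ± 0.13 on the log2 scale and its fenofibrate level by 4.36 ± 0.13. Among the shared genes, 190 of 287 that rose with ezetimibe and 35 of 72 that fell went further with the combination.

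Between the single drugs, 35 of the 60 shared genes differed, 28 of them further from DMSO with ezetimibe and 7 nearer, again only among genes past the listing threshold with both. Of the sterol genes raised by both, 5 that were less raised by ezetimibe than by fenofibrate had log2 differences of -0.98 ± 0.12 for MSMO1, -0.91 ± 0.08 for FDFT1, -0.84 ± 0.08 for DHCR7, -0.82 ± 0.08 for INSIG1 and -0.27 ± 0.08 for SREBF2 (adjusted p = 1.73e-05, 3.27e-06, 7.25e-06, 8.04e-06 and 0.0101), and for STARD4 the difference did not pass (-0.23 ± 0.15, adjusted p = 0.210). KLHDC7B (2.39 ± 0.36), FAM129A (2.11 ± 0.13), ALDH1L2 (1.64 ± 0.15) and CYP1A1 (1.27 ± 0.07) were more raised by ezetimibe. Mitotic genes listed with ezetimibe were found in the combination table less often than its other genes, 6 of 15 against 353 of 457 (Fisher's exact test, 2-sided, adjusted p = 0.0195). PLK1 and AURKA were among the 9 that were not listed there. The 15 genes lay near the listing threshold with ezetimibe, with a median log2 fold change of -1.12 and the largest fall at -1.37. They were not compared with other genes of similar change, so the test does not show a loss particular to mitotic genes. The combination table itself listed 15 of the 39 G2/M genes as lower.

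For the 49 genes in all 3 tables, 46 of them higher and 3 lower, the combination was tested against the sum of the single-drug log2 changes. It differed from the sum in 35 genes, lying further from DMSO in 8 and nearer in 27, with a median difference of -0.60. ATF3 exceeded the sum by 2.89 ± 0.17 (adjusted p = 7.28e-08), GDF15 by 1.23 ± 0.14 (adjusted p = 1.29e-05), DDIT3, a stress-induced transcription factor, by 1.22 ± 0.26 (adjusted p = 0.00167) and CXCL8 by 0.66 ± 0.12. KLHDC7B (-1.89 ± 0.47, adjusted p = 0.00418), CYP1A1 (-1.07 ± 0.10) and ASNS (-1.05 ± 0.27) fell short of it. HMOX1 was near the sum (0.06 ± 0.25, adjusted p = 0.840). These genes are those that changed by more than the listing threshold under every treatment, so the counts do not extend to other genes.

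**Figure D4:**
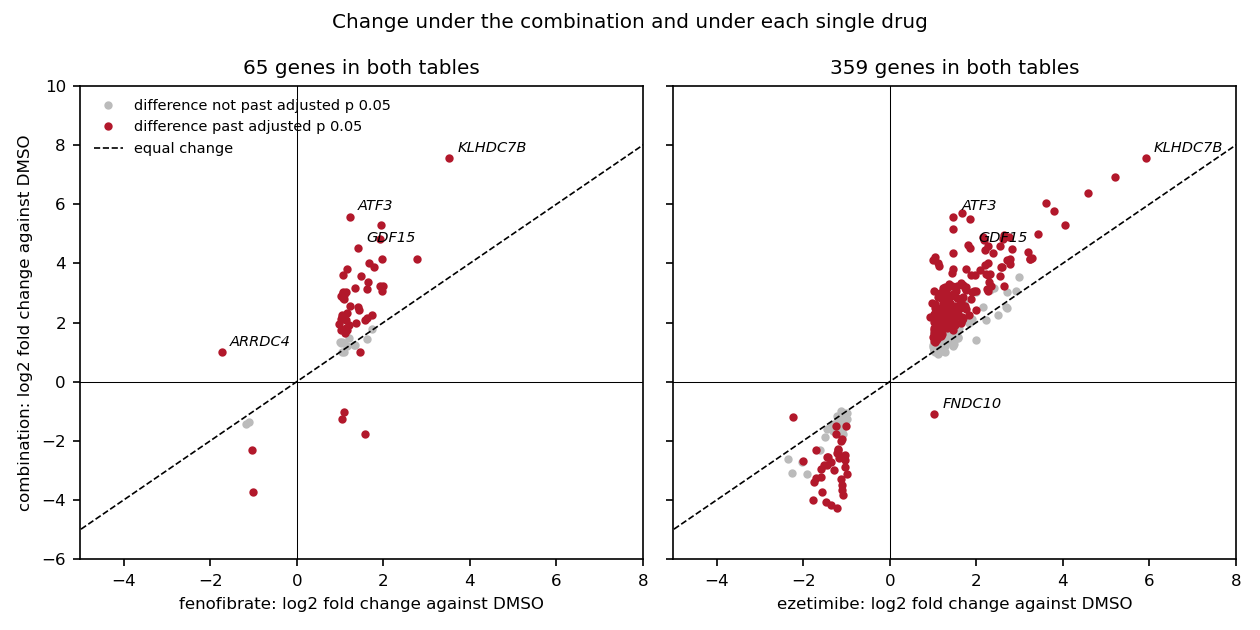
Log2 fold change against DMSO with the combination (vertical axis) and with fenofibrate (left) or ezetimibe (right) for genes in both tables, with a dashed line of equal change and red points for genes whose difference passed an adjusted p of 0.05. Genes with a combination change under 1 on the log2 scale are not in its table and cannot be plotted. Of the red points 46 of 51 on the left and 225 of 227 on the right lie on the same side of 0 with both treatments and further out with the combination. FNDC10 lies on the opposite side on the right, at -1.09 with the combination.

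The 3 lists overlapped beyond chance in direction and number. Fenofibrate and ezetimibe shared 57 higher genes where 2.79 would be shared by chance, 3 lower genes and 0 changed in opposite directions. The ezetimibe and combination tables shared 286 higher genes (55.6 by chance), 72 lower genes (11.2 by chance) and 1 changed in opposite directions. The fenofibrate and combination tables shared 57 higher genes (15.7 by chance), 4 lower genes and 4 changed in opposite directions. As all 3 tables use the same DMSO libraries, part of this excess can come from them. In simulated unchanged groups set against the same controls 66.2% of the 359 genes shared by the ezetimibe and combination tables had the same sign (at most 71.3% in 100 simulations), where the data had 99.7%. For the fenofibrate and combination tables the data had 93.85% (simulated at most 81.5%), and for the single drugs 100% (simulated at most 80%). The listed genes had been picked for a large change in both tables, and the simulated values had not. These shares therefore do not show how much of the overlap comes from the shared libraries. Genes found in 1 table alone numbered 26 for fenofibrate, 102 for ezetimibe and 3133 for the combination.

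Over the 33 lists, 404 memberships were listed in the 3 tables, and limma called all 404 both over all listed genes and when adjusted over the list alone. Markers of other cell types and states were on the lists as well. Luminal breast genes split into 5 of 24 higher with the combination, among them ESRP1, a splicing factor of epithelial cells with 0 reads in DMSO (at least 28.8-fold), GATA3 (104 ± 10.5 against 25.1 ± 9.18) and XBP1 (7102 ± 681 against 1747 ± 58.3), which is also on the unfolded protein response list, and 2 lower, GRHL2 and ERBB2 (adjusted p = 0.519 and 1). Of these 2, limma called 1 without DMSO replicate 2. Basal genes had 4 of 18 higher, among them KRT17 (269 ± 44.4 against 38.6 ± 4.13) and EGFR (4750.3 ± 1340.0 against 1338 ± 24.6), and MYLK and FOXC1 lower (adjusted p = 0.531 and 1). Fibroblast and endothelial markers had 4 of 14 lower, COL1A1 (262 ± 15.2 against 1021 ± 158), PDGFRB, ENG and PDPN (adjusted p = 0.113), and of the immune markers ITGAM alone was higher at a low level (57.8 ± 10.2 against 18.2 ± 5.86).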

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

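Of the tests in this part, those on the scaling of the tables, on the scaling of the combination libraries, on the sum of the single-drug changes and on regrouped libraries were chosen only after the results they measure were seen, and the others before.

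A few genes lay on opposite sides of DMSO under a single drug and under the combination, with a limma test of the difference between the treatments. ARRDC4, an arrestin-domain protein that fell with fenofibrate and rose with the combination, differed by 2.73 ± 0.17 on the log2 scale (combination minus fenofibrate, adjusted p = 1.22e-07), with 592 ± 109 against 295 ± 46.9 for the combination against DMSO. RTN4R, the Nogo receptor, differed by -2.32 (combination 42.7 ± 3.58 against 218 ± 23.9 with fenofibrate on one scale, adjusted p = 3.15e-07) and NOTUM, a WNT-inactivating enzyme, by -2.10 (combination 36 ± 1.53 against 157 ± 5.63 with fenofibrate, adjusted p = 2.07e-06). FNDC10 rose with ezetimibe and fell with the combination (combination minus ezetimibe -2.12, combination 89.8 ± 26.7 against 383 ± 35 with ezetimibe, adjusted p = 1.34e-06). For each of these 4 genes all 3 libraries of either treatment lay on its own side of all 3 DMSO libraries, and no explanation was tested for them one by one.

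The first pattern weighed is that 18 cholesterol genes rose with fenofibrate and 14 of them were not listed with the combination. Separate scaling of the 2 tables is argued against, since no DMSO library differed between them by more than 0.0411 on the log2 scale. A downward shift of all combination libraries stays open for the genes nearer the listing threshold. INSIG1, MSMO1, FDFT1 and DHCR7, at log2 2.01 to 2.13 with fenofibrate, would need a shift of about 1. Such a shift would take unchanged genes to about the listing threshold on the lower side. Only 7.27% of the genes the authors adjusted over were listed as lower, which argues against a shift as the sole cause for these genes. Of the other genes that fenofibrate raised by no more than the cholesterol genes' median, 70.7% (41 of 58) were in the combination table. However, 49 of the 65 genes shared by fenofibrate and the combination were also listed with ezetimibe. The effect of ezetimibe itself could keep such genes past the listing threshold despite a shift, so their presence cannot decide. Too few reads are argued against too, since 61.9% of the genes in the combination table had a DMSO mean under that of the lowest of the 14, MVK (273). Another candidate explanation left open is that adding ezetimibe may limit the sterol response to fenofibrate. This hypothesis needs the values of the 14 genes in the combination libraries, which are not in the table.

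The second pattern is the joint fall of the 13 mitochondrially encoded protein-coding genes with the combination. Scaling of the combination libraries is argued against, as 7.27% of the genes the authors adjusted over were listed as lower. A single library is argued against, as the least negative log2 fold change over the 13 genes and the 6 omissions of a library was -1.55, and so is a trend with gene length, as 36.6% (63 of 172) of the listed nuclear protein-coding genes of up to 1812 bases were lower. RNA integrity and the share of dying cells, which could also lower these transcripts, were not tested and stay open. So does an effect of the 2 drugs together on mitochondrial transcripts, as a hypothesis.

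The third pattern is that 27 of the 49 genes in all 3 tables lay nearer to DMSO with the combination than the sum of the single-drug changes, and 8 further away. Listing of genes whose single-drug change was overestimated by chance stays open, since the 12 genes changed by at least 1.5 on the log2 scale under both drugs, of which 10 (83.3%) lay below the sum by their own test, were picked on the same values that make up the sum. An offset of the combination libraries of about the median difference, -0.60, cannot be told apart from a smaller joint effect, because the combination table holds 0 genes with an absolute log2 fold change under 1 from which to read it. Less than additive action of the drugs may be the cause and stays open, as does a limit on how far these genes can rise.

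Regrouping the libraries of 2 groups of 3 gives 10 splits, too few for a share under 0.05. The real split called 102 genes for fenofibrate, 471 for ezetimibe, 3508 for the combination, 51 for the combination against fenofibrate, 227 against ezetimibe and 35 for ezetimibe against fenofibrate, each reached by 1 of 10 splits, the real one, and the highest of the other splits was 0 in every case. These genes had been listed for the real split. For the test against the sum, 2 of 100 groupings drawn from the 12 libraries called at least the real 35 genes, the real one included, and the highest of the others called 37. The 49 genes had also been listed for the real grouping, so this count does not decide whether chance can be excluded.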

How the results depend on the processing

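Tests with edgeR and DESeq2, with tables left unscaled, and of lists with a library left out were chosen after seeing the data. Of 4281 values under alternatives 4252 kept their direction and side of the threshold, or for counts stayed within 1.5 times, and none reversed. Of 230 named gene results 229 kept their call under every alternative run. The exception was CDH5 with ezetimibe, without DMSO replicate 2 (log2 -1.03, adjusted p = 0.0559). By edgeR 102, 471 and 3508 genes were called for fenofibrate, ezetimibe and the combination, and by DESeq2 102, 472 and 3506. All genes in these alternatives had been listed by the authors on the same libraries. That favours a call under any method, so the kept calls are no independent test of the processing. No setting without a filter was run, since the main setting has none.

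With the replicate number as a replicate block 102, 472 and 3508 genes were called. In none of the 3 tables did every treated library correlate best, over the deviations of genes from their group means, with the DMSO library of its own number, and in the combination table the correlations of libraries with the same number were 0.0916, -0.327 and 0.157. Between combination and DMSO libraries of different numbers they ran from -0.333 to 0.338, which a block on the number cannot take up.

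The filter on a mean of at least 50 changed counts by its construction, as it tests fewer genes. With it 216 of 295 genes were higher with ezetimibe and 1128 of 2303 with the combination. Higher list members became 0 with ezetimibe for PPARα targets, the BCL2 family and interferon, 1 for luminal genes and 4 for NF-κB. With the combination they became 1 for PPARα targets and glycolysis, 2 for histones, 3 for luminal genes and 0 for immune markers. Lower members became 0 with ezetimibe for NRF2, interferon and endothelial markers, and with the combination 0 for NRF2 and 1 for hypoxia, interferon and luminal genes. At 0.01 for the authors' adjusted p, 0 members remained for glycolysis with fenofibrate (higher) and, with ezetimibe, for the BCL2 family (higher), NRF2 and endothelial markers (lower), and 1 lower luminal gene with the combination, all by the stricter threshold itself. Leaving out 1 library at a time, lower luminal genes with the combination ranged from 1 to 2 and lower endothelial markers with ezetimibe from 0 to 1, in both cases with the lowest value without DMSO replicate 2, and the cause was not tested. Total calls then ranged from 100 to 102, 465 to 472 and 3474 to 3494. The listed genes alone limit what could change, since no gene outside the tables can enter.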

Other observations

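The tests on transcription factor families and the counts of gene classes were chosen only after the tables were seen. The deposited tables assign transcription factors to families, and 6 of 12 tests of their splits passed (Fisher's exact test, 2-sided, against the rest of the same table, adjusted over the 12). With the combination, 81 zinc finger factors of the C2H2 type were higher and 22 lower (adjusted p = 0.000201), and 15 factors of the bZIP type, ATF3, DDIT3, FOSL1 and JUN among them, were higher and 2 lower, JDP2 and DBP (adjusted p = 0.0304). The families were not compared with other genes of similar level. All 5 listed members of the E2F family were lower (adjusted p = 0.0304), as were 8 of 9 HMG box factors (adjusted p = 0.0199) and 8 of 10 forkhead factors, FOXM1 and FOXC1 among them (adjusted p = 0.0401). With ezetimibe, 6 of 9 listed basic helix-loop-helix genes were lower, 4 of which were ID1, ID2, ID3 and ID4, the inhibitors of that family (adjusted p = 0.0199).

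Non-coding genes in the combination table were mostly higher, which was not tested. The excess of higher genes in that table was carried by genes with low values, and these classes were not compared at equal level. Of 205 long intergenic RNAs 155 were higher and 50 lower, of 177 antisense RNAs 139 and 38, and of 87 transcribed unprocessed pseudogenes 79 and 8, where 1489 of 2741 protein-coding genes were higher (54.3%). Whether reads were assigned by strand is not given in the sources used here. The 15 mitochondrial transfer RNAs in that table were all lower, and the 5 with a mean of at least 50 had log2 fold changes from -3.11 to -1.98. The matrix list had LOX, CTGF, CYR61 and COL5A1 among its higher members and COL1A1, TGFB1 and COL6A1 lower with the combination (hypergeometric adjusted p = 1 in both directions), and COL5A1 rested on 13 reads against 0, at least 4.35-fold. Of the interferon list ISG20 (221 ± 24.8 against 15.8 ± 6.99) and IRF1 were higher and IFIT1 and BST2 (137 ± 31.4 against 529 ± 17.9) lower (adjusted p = 1), and of the splicing list SRSF2 alone was listed, as lower (1425 ± 184 against 3611 ± 436).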
